A study of Rattus norvegicus with 6 samples.

How the data were processed

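The samples were 6 DNase I sequencing libraries of cultured rat microglia, from 2 independent cultures in each of 3 groups (untreated, LPS and GCM). Per the labels, each culture came from 10 to 15 pups of 1 day of age, was grown for 2 weeks with 10% serum and rested for 48 h. LPS was given at 100 ng/mL for 6 h, and GCM, harvested from C6 cells after 24 h, was given for 6 h. Nuclei were digested for 10 min with 0.2 to 3.2 U of DNase I, and 3 concentrations went into the library. Cut ends were captured with a linker and sequenced as short tags.

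The authors name cutadapt 1.8.3, Bowtie 1.1.2, SAMtools, Picard 1.95, DiffBind and edgeR, with genome build rn5, but not the order or settings in which they were used. The authors deposited a table of raw counts of tags per region for the 6 libraries. The authors' comparison tables hold, per the file headers, a log2 fold change and mean log2 CPM, a likelihood ratio score, a p-value and its adjusted p-value (FDR), and CPM per library. The authors' CPM are scaled to the total of the whole library, since dividing by them gave 1 total per library, with 100% of values within 0.001 of a whole count. The hotspot lists deposited for each library give an interval and a score, which is the authors' and whose definition is not stated, used only to rank hotspots within a list, and their names state a false discovery rate of 0.01. The authors' tables also repeat per-library values of CPM per base, but these follow the order of regions and not that of their own lines, so they were not used.

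All 129499 counted regions, on 21 chromosomes and 1 to 4673 bp wide, had coordinates identical to the union over groups of the hotspot parts shared by both libraries of a group. A region thus needed hotspots in both libraries of at least 1 group. The 126640 regions in the authors' tables were those over 0.001 CPM per base in both libraries of at least 1 group. The authors' adjusted p-values were those of the Benjamini-Hochberg method, with a largest difference of 1.31e-14. Positions are printed with the first base counted from 1 and the last base included.

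Counts were tested in edgeR 4.0.16 under R 4.3.3 with all 6 libraries in 1 quasi-likelihood fit of group means. Regions were kept by the default filter of edgeR with a minimum count of 10, which left 126284 regions. Libraries were scaled by TMM, whose factors ran from 0.986 to 1.01, and tests were two-sided with Benjamini-Hochberg adjusted p-values and a threshold of 0.05. The common biological coefficient of variation was 5.63%. CPM were computed from counts in regions with TMM scaling, and the SE of a log2 fold change was its size divided by the square root of its F statistic. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 and bedtools 2.31.1 served for intervals and summaries, and an overlap of at least 1 bp counted as shared.

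Counts in regions were 11.1 M and 7.14 M in untreated libraries, 9.82 M and 12.4 M with LPS and 8.26 M and 12.1 M with GCM, and the median count per region was 56, 36, 51, 63, 41 and 64 in that order. The test was tried on simulated counts at these depths, with 200 regions changed per run. Counts were drawn independently per region with the dispersions that edgeR had estimated, so the rates below hold only under that model. Shared differences over broad stretches were not simulated, though the LPS libraries had them (chi-square per degree of freedom 7.92 in counts summed per Mb). It recovered 68%, 63% and 62.5% of 2-fold changes for LPS, GCM and GCM against LPS, and 94.5%, 90.5% and 87% of 3-fold changes. False calls numbered 13, 6 and 3 beside 136, 126 and 125 recovered regions at 2-fold, and 13, 8 and 6 beside 189, 181 and 174 at 3-fold, so for LPS the share of false calls at both folds was above the threshold of 0.05. Of 1.5-fold changes it recovered 15.5%, 14% and 9.5%, so most changes of that size were not detectable. Differences between the untreated libraries were close to counting error over all regions (chi-square per degree of freedom 0.979), lower than within LPS (1.25) and GCM (1.30), but exceeded it in counts summed per chromosome (16.0), and the untreated libraries were counted as 2 samples.

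Regions named in the text were chosen by rule: for LPS and for GCM against untreated cultures, the 10 increased and 10 decreased regions with the smallest p among those with an adjusted p under 0.05 and with both stimulated libraries on the same side of both untreated ones, and for GCM against LPS 5 in each direction. The rule also asked for an assigned gene, and that clause was dropped because the files assign none. The groups, tests, this rule and the first set of alternatives were chosen before the data were examined.

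Alternatives chosen in advance were size factors from DESeq2 1.42.0, totals in regions without composition correction, no filter on low counts, a minimum count of 20, the likelihood ratio test, DESeq2 itself, only the 4 libraries compared, a block for replicate number, leaving out each library, a 50% overlap, the better-scoring 50% of each hotspot list, the same number of top-ranked hotspots for the Jaccard index, and the authors' calls at 0.01. Those added after seeing the data were whole-library totals, the untreated libraries counted as 1 sample, offsets for region density and width or for mean abundance, a separate untreated library for each comparison, regions with a hotspot in all 6 lists, DESeq2 with the dispersions of edgeR or on the regions edgeR tested, all alternatives for regions changed by both stimuli, and the same number of top-ranked hotspots for shared, gained and lost hotspots.

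After seeing the data, the regions most raised in 1 stimulated library over 1 untreated library, as many as edgeR called, were also read in the libraries of the other stimulus over the other untreated library, with 0.5 CPM added before taking log2.

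The 15 gene lists fixed in advance, the shares of changed regions near promoters and the search for 10 motifs were not run, because no genome sequence or gene annotation of build rn5 was at hand. Sequence reads were not used here.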

Results

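Open chromatin was measured by DNase I sequencing in cultured microglia, the resident immune cells of the brain, taken from newborn Wistar rats. DNase I cuts DNA where it is not packed around nucleosomes, so a higher count of cut ends in a region means more accessible chromatin there. Cultures were left untreated, stimulated for 6 h with lipopolysaccharide (LPS, a bacterial cell wall component that triggers inflammatory activation), or stimulated for 6 h with glioma-conditioned medium (GCM, medium from the rat glioma line C6). Each of the 3 groups had 2 independent cultures. Libraries held 95.4 M and 65.2 M reads in the untreated group, 80.5 M and 102.5 M with LPS, and 60.1 M and 120.5 M with GCM. Of these, 7.14 M to 12.4 M counts per library fell in 129499 counted regions of the rat genome (build rn5), which had a median width of 370 bp and a summed length of 62.5 Mb. The share of reads in those regions was 11.7% and 10.9% in untreated libraries, 12.2% and 12.1% with LPS, and 13.7% and 10.0% with GCM (95% Wilson interval of the last, 9.999% to 10.01%, which covers counting error only). Values per region are CPM, that is counts scaled to each library's total in the counted regions, given as mean ± SD of 2 libraries, and the files do not assign regions to genes, so regions are named by position.

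The comparison of LPS with untreated cultures asks which chromatin regions open or close in inflammatory activation. After 6 h of LPS, 8470 regions became more accessible and 3963 less accessible, which is 9.85% of the 126284 regions tested. The region at 24651189 to 24652190 on chromosome 17 rose from 6.39 ± 0.677 to 19.5 ± 0.131 CPM, and the region at 39327709 to 39328154 on chromosome 10 rose from 2.32 ± 0.512 to 10.9 ± 0.681 CPM. The region at 51694018 to 51694403 on chromosome 8 fell from 8.85 ± 0.0251 to 2.95 ± 0.711 CPM. The median log2 fold change was 0.87 in increased regions and -0.74 in decreased ones, and 2977 increases but 595 decreases exceeded 2-fold.

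The 10 increased regions with the smallest p-values rose 3.09-fold to 5.08-fold and lay on 8 chromosomes. The increase on chromosome 17 was 1.63 ± 0.150 (log2 ± SE, n = 2 per group, adjusted p = 6.24e-09, edgeR), and that on chromosome 10 was 2.19 ± 0.204 (adjusted p = 6.24e-09, edgeR), with both LPS libraries above both untreated libraries. The largest fold among the 10 was at 14187919 to 14188380 on chromosome 1, from 1.64 ± 0.339 to 8.64 ± 0.0118 CPM. In GCM-treated microglia all 10 of these regions were less accessible than in LPS-treated microglia, and 2 of them, at 14187919 on chromosome 1 and at 163805757 on chromosome 2, were also increased by GCM over untreated cultures. Picking regions by their LPS p-values favours a difference between GCM and LPS. Of all 8470 LPS-increased regions, 4012 (47.4%) were lower with GCM than with LPS.

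The 10 decreased regions with the smallest p-values were 1.94-fold to 3.04-fold lower with LPS. Accessibility at 51694018 on chromosome 8 changed by -1.61 ± 0.201 (log2 ± SE, n = 2 per group, adjusted p = 7.74e-07, edgeR), and at 101817475 to 101818021 on chromosome 13 by -1.31 ± 0.167 (adjusted p = 1.24e-06, edgeR). With GCM the log2 changes of the 10 ran from -0.52 to -0.12 and did not pass the test (adjusted p from 0.0672 to 0.756, edgeR), and all 10 were higher with GCM than with LPS. The choice by LPS p-values favours this too, and 1244 (31.4%) of all 3963 LPS-decreased regions were higher with GCM than with LPS. On chromosome 16 an increased region of the list (11487501 to 11487909, 3.89 ± 0.0522 to 13.4 ± 0.818 CPM) and a decreased one (11553664 to 11554151, 11.9 ± 2.07 to 5.17 ± 1.31 CPM) lay 65.8 kb apart.

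Regions that opened with LPS started low: their median was 3.36 CPM in untreated cultures, against 5.30 CPM in regions not called, and in the GCM libraries, which shared the fit but are not part of this contrast, it was 4.10 against 5.39 CPM. Regions that closed started higher, at 6.61 CPM untreated and 5.69 CPM in the GCM libraries. Of the increased regions 3958 (46.7%) had no hotspot of DNase cutting in either untreated library, compared with 11.3% of regions not called, and 1309 (33.0%) of the decreased regions had none in either LPS library. The counted regions were built from the same hotspot lists, so these shares are not independent of the counts.

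The LPS calls came from a quasi-likelihood test in edgeR, and the number fell to 4411 without untreated replicate 1, 4636 without untreated replicate 2, 7205 without LPS replicate 2, and 789 (722 increased) in DESeq2. Scaling to whole-library totals gave 6975 regions, of which 90.2% were increased instead of 68.1%, and 3742 of the regions with a hotspot in all 6 lists were called.

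**Figure D1:**
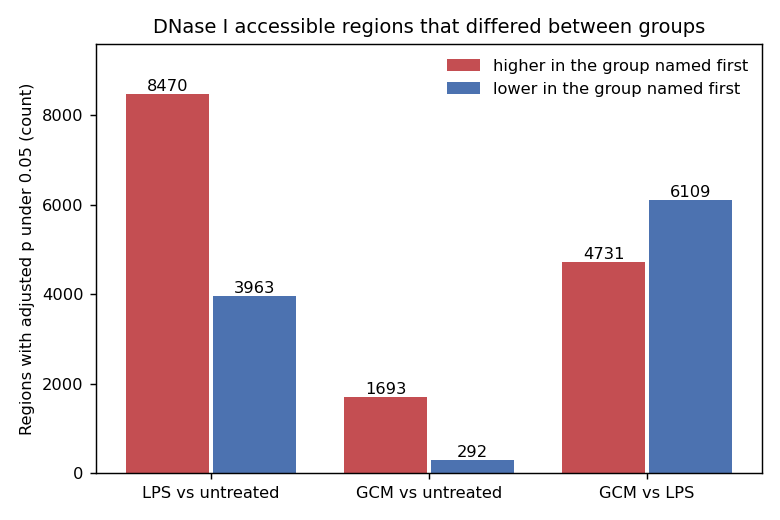
Bars give the number of regions with higher and with lower accessibility in each of the 3 comparisons (edgeR, adjusted p under 0.05, 126284 regions tested, 2 libraries per group). LPS changed 12433 regions, GCM changed 1985, and 10840 differed between GCM and LPS.

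The comparison of GCM with untreated cultures asks which regions open or close when microglia are exposed to factors released by glioma cells. GCM made 1693 regions more accessible and 292 less accessible, 1.57% of those tested. The region at 32571458 to 32571843 on chromosome 13 rose from 2.44 ± 0.0882 to 9.11 ± 1.25 CPM, and the region at 133591686 to 133592383 on chromosome 4 rose from 2.37 ± 0.575 to 9.28 ± 1.48 CPM. The region at 19047125 to 19047414 on chromosome 12 fell from 6.00 ± 0.633 to 2.34 ± 0.522 CPM. The median log2 change was 0.89 in increased regions and -1.004 in decreased ones, and 595 increases and 148 decreases exceeded 2-fold.

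The 10 increased regions with the smallest p-values rose 1.94-fold to 4.25-fold, and 7 of them lost the call in DESeq2. The increase at 32571458 on chromosome 13 was 1.91 ± 0.219 (log2 ± SE, n = 2 per group, adjusted p = 4.4e-06, edgeR), and the largest of the 10, at 4298134 to 4298405 on chromosome 6, was 2.09 ± 0.263 (adjusted p = 1.98e-05, edgeR). LPS also increased 573 (33.8%) of all 1693 GCM-increased regions, against the same untreated libraries, which can add calls to both lists. It increased 6 of the 10, among them 235868703 to 235869239 on chromosome 1, which held 2.35 ± 1.04 CPM untreated, 6.94 ± 0.814 with LPS and 8.50 ± 0.377 with GCM. The higher level with GCM than with LPS passed the direct test in 509 (30.1%) of all GCM-increased regions. It did so in 8 of the 10, whose choice by GCM p-values favours it. One such region, at 172034520 to 172035085 on chromosome 4, held 4.63 ± 0.592 CPM untreated, 5.25 ± 0.0417 with LPS and 10.9 ± 0.781 with GCM. Another, at 91268345 to 91269306 on chromosome 7, was the most accessible of the 10 and went from 11.8 ± 0.0299 to 22.8 ± 0.0885 CPM.

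Of all 292 GCM-decreased regions 121 (41.4%) were also decreased by LPS, against the same untreated libraries, which can add calls to both lists. The 10 decreased regions with the smallest p-values were 1.78-fold to 3.68-fold lower with GCM, and 8 of them were also decreased by LPS. All 10 lost the call without untreated replicate 1, without untreated replicate 2 and in DESeq2, and 9 lost it without GCM replicate 2. At 19047125 on chromosome 12 the change was -1.29 ± 0.229 (log2 ± SE, n = 2 per group, adjusted p = 0.00199, edgeR) with GCM and -1.35 ± 0.227 (adjusted p = 7.48e-05, edgeR) with LPS. The largest decrease, -1.88 ± 0.363 at 111023695 to 111023905 on chromosome 13 (adjusted p = 0.00411, edgeR), rested on 4 and 10 counts in the GCM libraries. The region at 233348359 to 233349107 on chromosome 1 was the only one of the 10 whose lower level with GCM than with LPS passed the direct test, at 10.0 ± 0.658 CPM untreated, 12.9 ± 0.960 with LPS and 5.45 ± 1.101 with GCM. Of all 292 decreased regions, 203 (69.5%) had no hotspot in either GCM library, and of the 1693 increased regions 597 (35.3%) had none in either untreated library.

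The number of GCM calls depended on single libraries: edgeR called 12 regions (0 decreased) without untreated replicate 1, 87 (1 decreased) without untreated replicate 2 and 33 (6 decreased) without GCM replicate 2, 1003 with the untreated libraries counted as 1 sample and 3333 with a block for replicate number. Scaling to whole-library totals gave 429 calls, 728 of the regions with a hotspot in all 6 lists were called, and DESeq2 called 3 regions, all increased, where edgeR called 1985.

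**Figure D2:**
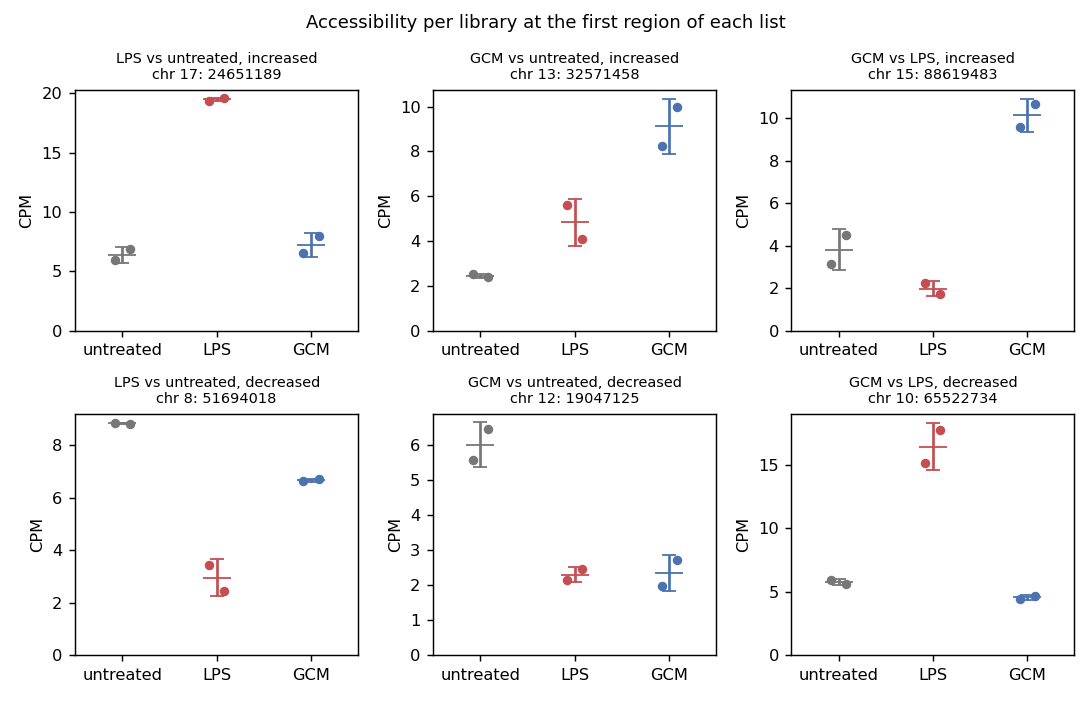
Points give CPM in each of the 6 libraries at the region with the smallest p-value of each direction in each comparison, with lines for the group mean and bars for the SD of 2 libraries. The chromosome 17 region stands at 19.5 CPM with LPS and at 7.23 CPM with GCM, while the chromosome 13 region stands at 4.83 CPM with LPS and 9.11 CPM with GCM.

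A direct comparison of the stimulated cultures asks where GCM and LPS leave chromatin in different states. Accessibility was higher with GCM in 4731 regions and higher with LPS in 6109, which is 8.58% of those tested. The region at 88619483 to 88620050 on chromosome 15 was 5.22-fold higher with GCM, at 10.1 ± 0.754 CPM against 1.97 ± 0.368 with LPS and 3.81 ± 0.955 untreated. The region at 65522734 to 65523323 on chromosome 10 was 3.62-fold higher with LPS, at 16.5 ± 1.88 CPM against 4.55 ± 0.174 with GCM and 5.76 ± 0.215 untreated.

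Of the 5 regions with the smallest p-values in each direction, the 5 that were lower with GCM had all been increased by LPS. Against untreated cultures their log2 changes with GCM ran from -0.34 to 0.07 and did not pass the test (adjusted p from 0.436 to 0.925, edgeR). The chromosome 10 region changed by -1.86 ± 0.158 from LPS to GCM (log2 ± SE, n = 2 per group, adjusted p = 5.83e-10, edgeR). Among the 5 that were higher with GCM, 4 had been decreased by LPS and 2 increased by GCM. The chromosome 15 region counted in both, and its difference was 2.38 ± 0.213 (adjusted p = 1e-09, edgeR), while 24494685 to 24495013 on chromosome 13 held 4.84 ± 0.501 CPM untreated, 1.68 ± 0.0669 with LPS and 5.88 ± 0.840 with GCM.

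The number of regions that differed between GCM and LPS in edgeR was 3933 without GCM replicate 2, 4844 without LPS replicate 2, 7079 without GCM replicate 1, 3222 when limited to regions with a hotspot in all 6 lists, and 712 in DESeq2. With whole-library totals it was 5433, and the share higher with GCM was 17.7% instead of 43.6%, while it was 51.5% in regions with a hotspot in all 6 lists (1660 higher, 1562 lower) and 15.4% in DESeq2 (110 higher, 602 lower).

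Set side by side, 573 regions were increased by both stimuli and 121 decreased by both. In the regions increased by both, median accessibility was 4.02 CPM untreated, 7.29 with LPS and 7.54 with GCM. In those decreased by both it was 4.19, 2.29 and 1.93 CPM. Regions increased by both made up 33.8% of the GCM-increased regions and 6.77% of the LPS-increased ones, and independent lists of these lengths would share 113.6. Regions decreased by both were 41.4% of the GCM-decreased regions, and independent lists would share 9.16. Both comparisons shared the untreated libraries, which can add regions to both lists. Simulations of unchanged groups made 0 calls for LPS and a mean of 0.05 for GCM, so they do not measure how many. In edgeR 10 regions were increased by both and 0 decreased by both without untreated replicate 1, 36 and 0 without untreated replicate 2, 16 and 5 without GCM replicate 2, and 909 and 330 with a block for replicate number. Regions decreased by both numbered 61 without LPS replicate 2 and 43 without GCM replicate 1, and DESeq2 called 2 regions increased by both and 0 decreased by both.

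Another 7896 regions were increased by LPS and not called with GCM, with medians of 3.31 CPM untreated, 6.32 with LPS and 3.87 with GCM. In 3997 of these the level with GCM was below that with LPS by the direct test. Of the 1118 regions increased by GCM and not called with LPS, with medians of 3.80, 4.67 and 6.92 CPM, 499 were higher with GCM than with LPS. The remaining regions of these groups were not shown to differ between the stimuli. Both groups were picked by calls from the same libraries, which favours a difference in the direct test. To keep the controls apart, the 8470 regions most raised in an LPS library over an untreated library were read in the GCM libraries over the other untreated library. There they stood 0.08 to 0.23 (log2) above the median of all regions over the 4 choices of libraries, and 62.1% to 72.9% of them lay above it. The 1693 regions most raised by GCM stood 0.20 to 0.28 above it with LPS, and 73.4% to 80.8% lay above it.

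Over the 126284 regions, which are not independent replicates, the log2 changes with LPS and GCM had a Pearson r of 0.484. Simulated unchanged groups, with all libraries drawn anew and the drawn untreated libraries shared by both comparisons, gave a mean of 0.535. The covariance of the log2 changes was 0.0684, above the highest simulated value of 0.0309. Counts were drawn independently per region. The draws lacked the differences over broad stretches that the untreated libraries had (chi-square per degree of freedom 2.08 in counts summed per Mb). Such differences in shared untreated libraries can raise the covariance, so its excess does not measure a shared response. With a separate untreated library for each comparison r was 0.275 or 0.233, taken from differences in log2 CPM instead of the edgeR fit. In that same measure r was 0.481 when both comparisons used untreated replicate 1 alone, and 0.643 when both used untreated replicate 2 alone. In edgeR r was 0.667 without untreated replicate 1 and 0.385 without GCM replicate 2.

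**Figure D3:**
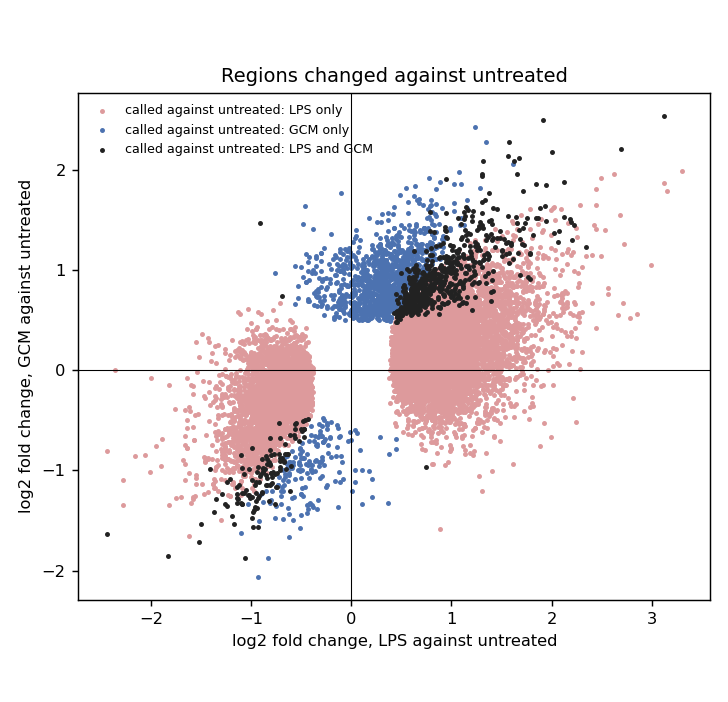
Each point is a region called against untreated cultures by LPS, GCM or both, placed by its log2 fold change with LPS (horizontal) and with GCM (vertical) and coloured by class. The plot holds 573 regions increased by both, 121 decreased by both and 3 called in opposite directions.

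Between libraries, Pearson correlations of log2 CPM across regions were 0.963, 0.968 and 0.966 within the untreated, LPS and GCM groups and 0.908 to 0.952 between groups. The first principal component (41.0% of the variance) separated LPS libraries from all others, and the second (26.2%) separated GCM from untreated libraries.

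Hotspots, the stretches of dense cutting listed by the authors for each library, numbered 160868 and 107489 in untreated cultures, 138554 and 152869 with LPS, and 125497 and 136057 with GCM. These lists covered 77.7, 46.2, 66.7, 74.6, 62.3 and 65.8 Mb in the same order. Hotspots found in both LPS libraries and in neither untreated one numbered 11547, and 4450 were found in both untreated libraries and in neither LPS one. For GCM these counts were 5854 and 4565, and all of these counts depend on list length and carry no test.

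The share of hotspots also found in the partner library was 67.7% ± 20.9 in the untreated group, 72.1% ± 5.59 with LPS and 73.4% ± 3.63 with GCM (mean and SD of both directions of the single pair in each group). In the untreated pair, 52.9% of the longer list and 82.5% of the shorter list were found in the other. The base-pair overlap of lists (Jaccard index) was 0.531 in the LPS pair and 0.540 in the GCM pair, but 0.437 in the untreated pair, which lay within the range of 0.430 to 0.522 between groups. The mean was 0.502 within groups and 0.483 between groups. The difference of 0.0197 was the largest among the 15 ways to pair 6 libraries (exact permutation test, one-sided, p = 0.0667, the smallest p this design allows). The exact permutation p was 0.2 in the better-scoring 50% of each list and 0.467 without LPS replicate 2.

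In the authors' deposited tables, 12357 regions were changed by LPS (8138 increased and 4219 decreased) and 2303 by GCM (1889 increased and 414 decreased) at an adjusted p under 0.05. Of these regions of the authors' deposited tables, 11710 (94.8%) and 1879 (81.6%) were also called here in edgeR with the same direction, and 0 with the opposite direction. At an adjusted p under 0.01 the counts in the authors' deposited tables were 6066 and 659, of which 99.2% and 96.4% were called here, where the threshold stayed at 0.05.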

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

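The tests of runs of regions against shuffled calls, with and without offsets, were chosen after the result was seen, and the other tests in this part were written down before their results.

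LPS and GCM moved 3 regions in opposite directions relative to untreated cultures in edgeR, and 2 of these regions fall outside the rule for named regions and were picked after their values were seen. The region at 88619483 to 88620050 on chromosome 15 differed by 2.38 ± 0.213 (GCM against LPS, log2 ± SE, adjusted p = 1e-09, edgeR), with -0.91 for LPS and 1.47 for GCM against untreated. The region at 220588164 to 220588657 on chromosome 1 differed by 1.43 ± 0.201 (adjusted p = 4.75e-06, edgeR), at 4.83 CPM untreated, 2.91 with LPS and 7.87 with GCM. The region at 139517071 to 139517424 on chromosome 7 differed by -1.71 ± 0.198 (adjusted p = 1.68e-07, edgeR), at 5.73 CPM untreated, 9.31 with LPS and 2.81 with GCM. Since the regions were picked for opposite calls, a difference between the stimuli follows from that choice and adds no independent evidence. The single calls depended on the setting: on chromosome 1 the LPS call passed in 12 and the GCM call in 13 of the 20 alternatives that held the region. The number of regions called in opposite directions was 0 without untreated replicate 1, without untreated replicate 2, with whole-library totals, among regions with a hotspot in all 6 lists and in DESeq2. It was 1 without GCM replicate 2, 5 without GCM replicate 1, 9 without LPS replicate 1, and 13 with a block for replicate number.

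LPS-increased regions lay in runs along chromosomes: 775 of the 8470 fell in 165 runs of at least 4 with gaps of at most 25 kb. Clustering of the tested regions themselves is argued against as the whole cause, since the highest of 1000 shuffles within 5 Mb windows and bins of equal abundance gave 92 runs. A smooth trend with region density and width is argued against in the same way, since 182 runs were left with offsets for it and the highest shuffle gave 107. Broad differences between single libraries stay open as a candidate explanation for LPS replicate 2. The 8470 regions most raised in it over LPS replicate 1 made 516 runs, more than in any LPS over any untreated library. Over untreated replicates 1 and 2, LPS replicate 2 made 217 and 227 runs, but LPS replicate 1 made only 105 and 94. The other 5 orderings of libraries within groups made 42 to 91, fewer than any of these but close to LPS replicate 1. Shuffles of the picked regions gave means of 51.2 to 62.05 runs for those 5 orderings. The shuffled means over untreated replicates 1 and 2 were 67.9 and 68.55 for LPS replicate 1, and 75.8 and 73.2 for LPS replicate 2. For LPS replicate 2 over LPS replicate 1 the shuffled mean was 178.6. LPS replicate 1 is thus not shown to exceed the orderings within groups. The excess of runs in single libraries thus lay mostly in LPS replicate 2. A response to LPS of whole chromatin domains also stays open and was not tested.

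GCM-increased regions were commoner where counted regions were sparse: 2.78% (351 regions) in the sparsest of 10 bins and 0.483% (61 regions) in the densest. The ratio was 5.75 (95% interval 4.38 to 7.55). Intervals in this paragraph cover only error from sampling regions, which are not independent replicates, and not the spread between libraries. Decreased regions were also commoner in the sparsest bin than in the densest, at 0.364% and 0.127% with GCM and 3.66% and 2.37% with LPS. LPS-increased regions made up 6.24% and 5.88%, with 7.29% in a bin between. With offsets for density and width the ratio fell to 3.44 (2.72 to 4.37), so a smooth trend of this kind may account for part of it but not, at these values, for the whole, which needed a ratio under 1.5. That interval reaches below the ratio of 3 set in advance as the mark against this explanation. More power from higher counts is argued against, since counts were lower where regions were sparse. The median was 3.82 CPM in the sparsest bin and 6.43 CPM in the densest. When bins were weighted to equal mean CPM the ratio was 6.14 (4.72 to 8.62). An effect of GCM on regions in sparse surroundings stays open and was not tested.

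Few GCM calls were left without GCM replicate 2: 33, against 1573 without GCM replicate 1. A signal of GCM replicate 2 alone is argued against, since the 1693 regions most raised in it over an untreated library stood 0.38 and 0.42 (log2) above all regions in GCM replicate 1 over the other untreated library. Regions picked in the same way in GCM replicate 1 stood 0.40 and 0.26 above all regions in GCM replicate 2. Lower depth of GCM replicate 1 as the whole cause is argued against as well: GCM replicate 2 thinned to its counts gave a mean of 862 calls when it stood alone, 26.1 times as many. A stronger response in that culture and a difference in library quality both stay open and were not tested. The share of reads in regions was 13.7% in GCM replicate 1 and 10.0% in GCM replicate 2.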

How the results depend on the processing

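Whole-library totals, the untreated libraries as 1 sample, both kinds of offsets, regions with a hotspot in all 6 lists, separate untreated libraries, DESeq2 with the dispersions of edgeR or on the regions edgeR tested, top-ranked hotspots for shared, gained and lost hotspots, and all alternatives for regions changed by both stimuli were chosen after seeing the data. Over the counts, shares and correlations, 96 values under alternatives stayed within the limits set for them and 75 moved. The limits were 1.5 times for a count, 1 SD for a share or correlation, and a value above 0 for the Jaccard difference. For a share the SD was that of both directions of the single pair in the group. For the correlation it was the SD of the values found on leaving out each library, which were themselves among the values judged. Neither SD measures spread between cultures, so the tally depends partly on how the limits were built. The Jaccard limit used neither a p-value nor the size of the difference. For the named regions 930 results kept their direction and threshold, 79 kept direction but lost the threshold, all of these for GCM against untreated, and 0 reversed. Of the 20 regions named there, 17 lost it in DESeq2 on either set of regions, 17 without untreated replicate 1, 11 without GCM replicate 2, 10 without untreated replicate 2, 4 without GCM replicate 1 and 3 with whole-library totals. No region was called in opposite directions by edgeR and any alternative.

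Counts of changed regions moved as follows for LPS, GCM and GCM against LPS. DESeq2 called 789, 3 and 712 regions, and 791, 3 and 713 on the 126284 regions edgeR tested. On that same set it called 12693, 2297 and 11154 with the dispersions of edgeR, so its own dispersions are the cause: 83.4% of regions lay at its floor and its median trend was 0.0378 against 0.00206 in edgeR. Whole-library totals gave 6975 (6290 increased), 429 and 5433 (961 higher with GCM), with a median shift for LPS of 0.09 (log2). This scaling carries the share of reads in regions into the comparison, which was 12.2% and 12.1% with LPS against 11.7% and 10.9% untreated. Why the shares differed, and why the number of calls fell, was not tested. Regions with a hotspot in all 6 lists gave 3742, 728 and 3222 calls, with 69548 regions to choose from. Counting the untreated libraries as 1 sample gave 1003 for GCM, by its construction with fewer samples. A block for replicate number gave 14441, 3333 and 12670, where replicate differences correlated between groups by 0.0484, 0.100 and 0.000999. The labels state no pairing and chromosome X was higher in replicate 2 of all 3 groups, so whether the numbers pair cultures stays open.

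Regions increased and decreased by both stimuli numbered 2 and 0 in DESeq2 on either set of regions, 139 and 23 with whole-library totals, 302 and 62 with the untreated libraries as 1 sample, 230 and 8 among regions with a hotspot in all 6 lists, and 909 and 330 with the block. Those decreased by both were 214 in the likelihood ratio test and 184 with density offsets. Without each library they ran from 10 to 619 and from 0 to 100.

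Leaving out each library gave 4411 to 12872 calls for LPS, 12 to 2648 for GCM and 3933 to 9751 for GCM against LPS, where a lone library is assumed to vary like the other groups. The lowest counts came without untreated replicate 1 for LPS and GCM and without GCM replicate 2 for GCM against LPS. The correlation of effects ran from 0.385 to 0.667. With separate untreated libraries it was 0.275 and 0.233, where the comparisons share no counts and each rests on a single untreated library. These values came from differences in log2 CPM. In the same measure the correlation was 0.481 and 0.643 with 1 untreated library shared by both comparisons. Gained hotspots ran from 13322 to 42391 for LPS and 7230 to 30738 for GCM, and lost ones from 6860 to 46094 and 7132 to 50127, since a lone list meets a looser rule. For hotspots found in both replicates no value is left without 1 of them.

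The better-scoring 50% of each list gave 5019 and 1570 gained and 1656 and 1343 lost hotspots for LPS and GCM, by construction from shorter lists. Shared hotspots for LPS and GCM were 66.3% and 67.8% with a 50% overlap, 86.4% and 87.0% in the better-scoring 50%, and 80.7% and 79.4% in equal numbers of top-ranked hotspots. The Jaccard difference stayed positive under every alternative run, at 0.00278 to 0.0537, with an exact permutation p up to 0.467. Calls in the authors' deposited tables at 0.01 were 6066 and 659, by the stricter threshold. Size factors, filters, offsets, the likelihood ratio test and fitting only 4 libraries kept the counts of changed regions in all 3 comparisons within 1.5 times. Gene lists, promoter shares and motifs were not run. Depth limits small changes: 14% of simulated 1.5-fold changes were recovered for GCM.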

Other observations

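The runs and shares described here were looked for after seeing the data.

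The longest runs of LPS-increased regions held 10 regions each, and the longest run in 1000 shuffles held 17, so only the number of runs, not their length, exceeded the shuffles. At 70376749 to 70448033 on chromosome 10, 10 of 25 tested regions were increased. Over these 10 alone, which were picked by their LPS call, the median log2 change was 0.88 with LPS and 0.11 with GCM. At 27674069 to 27773476 on chromosome 11, 10 of 14 tested regions were increased. Over these 10 alone, picked in the same way, the median was 1.24 with LPS and 0.41 with GCM. GCM-increased regions formed 15 runs of at least 4, and the highest of 1000 shuffles gave 9, but the longest held 5 regions and shuffles reached 10. At 19385960 to 19401139 on chromosome 11 all 5 tested regions were increased by GCM, 2 of them also by LPS. A run at 60151279 on chromosome 9 was shared, with 7 regions increased by LPS and 5 by GCM, 4 of them by both. LPS-decreased regions formed 6 runs, and 372 of 1000 shuffles gave as many.

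By chromosome, the share of tested regions increased by LPS was highest on chromosome 11 (8.63%) and lowest on chromosome 12 (3.86%), and the share increased by GCM was 0.209% on chromosome 12 and 2.04% on chromosome X. Counts on chromosome X were a larger share of all counts in replicate 2 than in replicate 1 of each group, at 1.27% and 1.20% untreated, 1.24% and 1.19% with LPS, and 1.26% and 1.21% with GCM.

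Hotspots in both libraries of a single group and in no other library marked 7283 regions for LPS, 2886 for untreated cultures and 2468 for GCM, and 69548 regions (53.7%) had a hotspot in all 6 lists.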
